A study of Homo sapiens with 24 samples.

How the data were processed

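p53 ChIP-seq was run on phytohaemagglutinin-stimulated T lymphocytes of 4 healthy donors after DMSO, doxorubicin or nutlin-3. The authors deposited 1 list of p53 peaks for each of the 12 immunoprecipitates, and the lists give chromosome, start and end with no score, height or p-value. Per the submitters' processing notes, Bowtie 0.12.8, Picard 1.86 and bedtools 2.17.0 were used with genome build hg19, without a statement of what each tool did. The peak caller and its threshold are not given in the sources used here, nor is the read depth. Starts lie in steps of 10 bp and widths run from 201 to 1701 bp, with a median of 201 bp in every list, so a width above 201 bp is the only trace of a stronger or broader signal. Each list came from 1 donor and 1 treatment, and nothing was pooled per the labels. A list called from a deeper or better enriched library is longer at the same binding, so presence or absence of a peak is not a level of binding, and a missing peak does not show that p53 was absent.

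Because the donors are people, only the 22 autosomes were used, and 486 of the 22994 peaks, those on other chromosomes and on unplaced contigs, were left out. The planned rule set aside fewer regions, but it needed an hg19 gene annotation. The gene table used here belongs to assembly GRCh38.p14, so genes, promoters and p53 motifs could not be assigned. The planned shares of peaks with a motif or near a promoter, and the counts for 11 gene lists fixed beforehand, were therefore not run. The table served only to count protein-coding genes per chromosome. Positions are in hg19 and 1-based.

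Peaks of all 12 lists were merged into regions when they overlapped by at least 1 bp, and a donor had a region when its list held a peak in it. Groups, donors and replicate numbers come from the labels. The number of peaks was compared between treatments on the log2 scale with exact two-sided permutation tests over all 70 assignments of 4 and 4 lists, adjusted by Benjamini-Hochberg over the 3 pairs. The smallest p such a test can give is 0.0286. Regions were compared by Fisher's exact test per region with Benjamini-Hochberg adjustment, and by counts of regions with a peak in all 4 donors of a treatment and 0 of the other. Repeated regions were those in 3 or more donors, set against 100 random placements of every list within its chromosomes. Overlap between 2 lists was the number of common regions divided by the regions of the shorter list. It was tested by exact permutation of treatments within donors (1296 relabellings) and of donors within treatments (576 relabellings). Intervals on shares are Wilson 95% intervals and cover counting error only.

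The same donor gave a list in each treatment, per the labels, so replicate numbers pair the lists. The correlation of the donors' deviations in log2 peak number was 0.893 between DMSO and doxorubicin, 0.206 between DMSO and nutlin-3 and 0.176 between doxorubicin and nutlin-3. The unpaired tests are the main ones and the paired sign-flip test, whose smallest p is 0.125, is an alternative. Up to 15 regions were named per pair of treatments, fixed beforehand as those with the largest difference in donors, then by mean within-list percentile of peak width and then by position.

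The main tests, the naming rule and most alternatives were fixed before the data were examined. Alternatives were leaving out each donor or list, keeping only peaks wider than the median, taking the same number of widest peaks, trimming peaks to 200 bp, merging peaks within 500 bp, other donor criteria, covered length, the Jaccard index and the paired tests. Among the widest peaks, those of equal width were taken at random, in a single draw. Only 3.42% to 14.9% of a list's peaks were wider than 201 bp, so many of those taken had the narrowest width. Added after the lists were seen were the core regions, the pooled test of drug lists and random thinning to at most 796 peaks. So were the broader criterion as a result of its own and single lists left out. Exact tests of repeated region counts between treatments were also added then, unpaired, within donors, and over 81 choices of the DMSO lists. Merging and counting were tested on simulated lists with 200 regions planted, at slightly shifted positions, in every list of 1 treatment, and 200 were recovered for each pair of treatments. This checks the bookkeeping and gives no error rate for real lists. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 were used.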

Results

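The series mapped where the transcription factor p53 sat on the genome of human T lymphocytes, the white blood cells that recognise antigens, before and after 2 drugs that raise p53 by different routes. Lymphocytes from 4 healthy donors were stimulated to divide with the plant lectin phytohaemagglutinin for 48 h and then given 1 of 3 treatments for 24 h. Doxorubicin (0.3 ug/ml) is a chemotherapy drug that traps topoisomerase II on DNA and causes strand breaks. Nutlin-3 (10 uM) blocks the binding of p53 to MDM2, the ubiquitin ligase that marks p53 for degradation, without damaging DNA. Control cultures received 0.1% DMSO, which was the solvent of nutlin-3, whereas doxorubicin was given in water, so the DMSO cultures were the matched vehicle for nutlin-3 only. p53 was immunoprecipitated with the antibody DO-1 from cross-linked chromatin, and the DNA was sequenced (ChIP-seq).

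The 24 samples were 12 p53 immunoprecipitates, 1 per donor and treatment, and 12 input DNA libraries, which were not analysed here. Each immunoprecipitate had 1 peak list, so every treatment had 4 lists from 4 donors. Donors are called replicates 1 to 4 and the same number is the same donor in every treatment. The autosomal lists held 796, 4264, 117 and 1094 peaks with DMSO in replicates 1 to 4. They held 1916, 2099, 221 and 1822 peaks with doxorubicin, and 1098, 2057, 1754 and 5270 with nutlin-3. The number of reads behind each list was unknown, so differences in list length could not be separated from differences in sequencing depth or in the yield of the immunoprecipitation. Merging the peaks of all 12 lists gave 12302 regions, of which 8603 (69.9%) had a peak in 1 list alone.

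p53 regions found again in several donors were more numerous after either drug than in DMSO. A peak in 3 or more of the 4 donors was present at 28 regions with DMSO, 721 with doxorubicin and 969 with nutlin-3. All 4 donors had a peak at 4 regions with DMSO, at 172 with doxorubicin and at 440 with nutlin-3. Of the 28 DMSO regions, 24 also had a peak in 3 or more of the 8 drug lists. Random placement of each list on its own chromosomes gave 0 regions in 3 or more donors in each of 100 placements, for every treatment. For 2 or more donors the counts were 266, 1235 and 1952, against at most 6, 6 and 15 in the random placements. The placement was uniform along each chromosome, so any lists that favour the same parts of the genome would exceed it. It cannot tell p53 sites from other shared regions. Of the 266 DMSO regions in 2 or more donors, 96 also had a peak in 3 or more drug lists. Thinning all lists at random to at most 796 peaks, a setting added after the lists were seen, left a mean of 7.39 DMSO, 107 doxorubicin and 105 nutlin-3 regions in 3 or more donors. The lists of replicate 3 with DMSO (117 peaks) and doxorubicin (221) stayed shorter, so list lengths were not made equal. Without 1 donor, when all 3 that remained had to have the peak, the counts were 5 to 17, 173 to 717 and 445 to 871. The DMSO count was the lowest in each of these settings, and the doxorubicin and nutlin-3 counts were close to each other after thinning. In tests added after the lists were seen, the excess over DMSO of 693 regions with doxorubicin and 941 with nutlin-3 did not pass the threshold (exact permutation p = 0.0857 for each, adjusted p = 0.129). Nor did it pass when treatments were exchanged within donors, although each p was then the smallest that exact test can give (adjusted p = 0.188). Nutlin-3 exceeded doxorubicin by 248 regions (exact permutation p = 0.514, adjusted p = 0.514), which was -224 without replicate 3. When 1 of the 3 lists of each donor was called DMSO in all 81 ways, the real choice and 1 other gave the lowest count of 28 (exact one-sided permutation p = 0.0247).

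**Figure D1:**
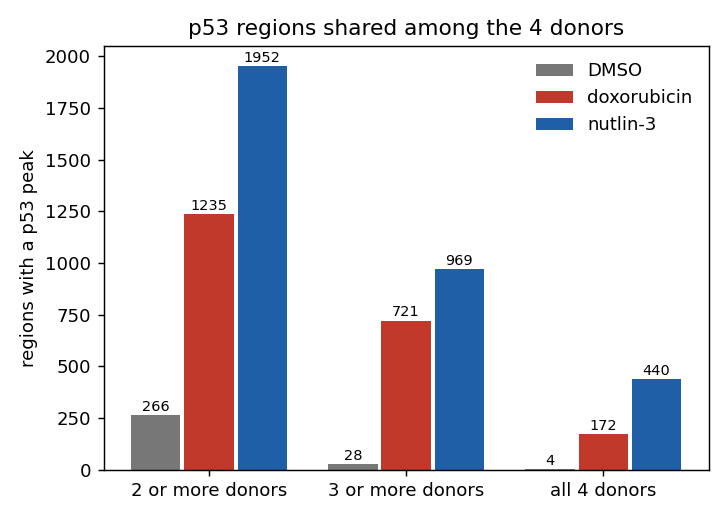
Number of regions with a p53 peak (y axis) in 2 or more, 3 or more, or all 4 donors (x axis), with 1 bar per treatment and its count above it. The 3 or more donor counts were 28 with DMSO, 721 with doxorubicin and 969 with nutlin-3.

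A few regions had a peak in every donor and treatment. Peaks in all 12 lists, DMSO included, were found at 4 regions of the human genome build hg19, which were chr1:181104151-181104391, chr12:19584851-19585121, chr15:63449371-63449651 and chr19:6577451-6577751. A further set of DMSO regions had a peak in 3 DMSO donors and in all 4 donors of both drugs. Among them were chr6:36644051-36644551, chr10:90750231-90751651, chr11:47236451-47236691, chr8:128807031-128808191, chr11:65188071-65188931 and chr1:212769811-212770181. The region chr12:69202611-69202831 had a peak in 2 DMSO donors and in all 8 drug lists. Altogether 142 regions had a peak in all 8 drug lists, and 1 of these, chr4:6266151-6266711, had none in any DMSO list. Of the rest, 41 had a peak in 2 or more DMSO lists and 100 in 1, and all 100 of these DMSO peaks came from the same list. These examples were chosen after their values were seen, apart from chr4:6266151-6266711. No gene is given for any region because the gene table used here belongs to another genome build.

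The first comparison asked which regions had a p53 peak with doxorubicin and not with DMSO. Regions with a peak in all 4 doxorubicin donors and in 0 of 4 DMSO donors numbered 4, and 0 regions had the reverse. They were chr15:52850231-52850891, chr1:111758471-111759051, chr20:36023251-36023571 and chr4:6266151-6266711. The first 3 of these also had a peak in 3 nutlin-3 donors, and the last had one in all 4. With the broader criterion of 3 or more donors against at most 1, 649 regions were higher with doxorubicin and 6 were higher with DMSO. Few regions could have had the reverse, as only 4 were in all 4 DMSO donors and 28 in 3 or more. The small reverse counts therefore do not measure how often a peak was lost. Regions with 4 doxorubicin donors and 1 DMSO donor included chr11:5710951-5712111, chr5:135443891-135444351, chr6:106545791-106546591, chr8:8220091-8221151 and chr10:129661471-129661971. Regions with 3 doxorubicin donors and 0 DMSO donors included chr14:69152251-69152721, chr5:40429711-40430031, chr4:176935971-176936951, chr2:68971681-68971991 and chr5:72250951-72251311.

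Counted within donors, 280 regions had a peak with doxorubicin and not with DMSO in at least 3 donors, with 0 donors the other way. The reverse, open only to the 28 regions in 3 or more DMSO donors, was found at 0 regions. By Fisher's exact test per region, 0 of 8641 regions passed after Benjamini-Hochberg adjustment (smallest adjusted p = 1, unadjusted p = 0.0286 for 4 regions), since 4 lists against 4 cannot give a smaller p. The geometric mean number of peaks was 1128 with doxorubicin and 812 with DMSO, a log2 ratio of 0.47 (exact two-sided permutation p = 0.714, adjusted p = 0.714, n = 4 and 4). This difference was smaller than the spread between donors. The strict count of 4 rested on single lists, because it was 164 without doxorubicin replicate 3, whose list was short, and 119 without 1 of the DMSO lists, while the broader count of 649 was 120 without doxorubicin replicate 1, 2 or 4, when all 3 lists left had to hold the peak. With peaks wider than the median alone the counts were 0 and 13.

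The second comparison asked the same of nutlin-3, which raises p53 without DNA damage. Regions with a peak in all 4 nutlin-3 donors and in 0 of 4 DMSO donors numbered 75, and 0 regions had the reverse. Among those named by rule were chr1:169553791-169554191, chr5:142580251-142580731, chr4:26408271-26408691, chr12:25864071-25864751 and chr17:33788251-33788651, each with a peak in 3 doxorubicin donors as well. The regions chr19:51951551-51952051, chr12:956951-957941 and chr6:44652951-44653371 had a peak in 2 doxorubicin donors. In 3 or more nutlin-3 donors against at most 1 DMSO donor there were 901 regions, and 4 in the opposite direction. As above, only 4 regions were in all 4 DMSO donors and 28 in 3 or more, which capped the reverse counts. Of the 15 regions named for this pair, 13 had a peak in 2 or more doxorubicin donors, and chr19:16003571-16003951 and chr2:15317251-15317551 had none in any doxorubicin or DMSO list.

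The count within donors was 683 regions with nutlin-3 and not DMSO, and 0 the other way, where at most 28 could be counted. Fisher's exact test per region passed 0 of 10850 regions after Benjamini-Hochberg adjustment (smallest adjusted p = 1, unadjusted p = 0.0286 for 75 regions). The geometric mean number of peaks was 2138 with nutlin-3 against 812 with DMSO, a log2 ratio of 1.40 (exact two-sided permutation p = 0.257, adjusted p = 0.714, n = 4 and 4), within the spread between donors. The strict count was 396 without 1 of the DMSO lists and 315 without nutlin-3 replicate 1, and the broader count of 901 was 429, 446 and 401 without nutlin-3 replicates 2, 3 and 4. With peaks wider than the median alone the counts were 1 and 20. With the same number of widest peaks from every list, equal widths taken at random and shorter lists whole, the strict count was 5.

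**Figure D2:**
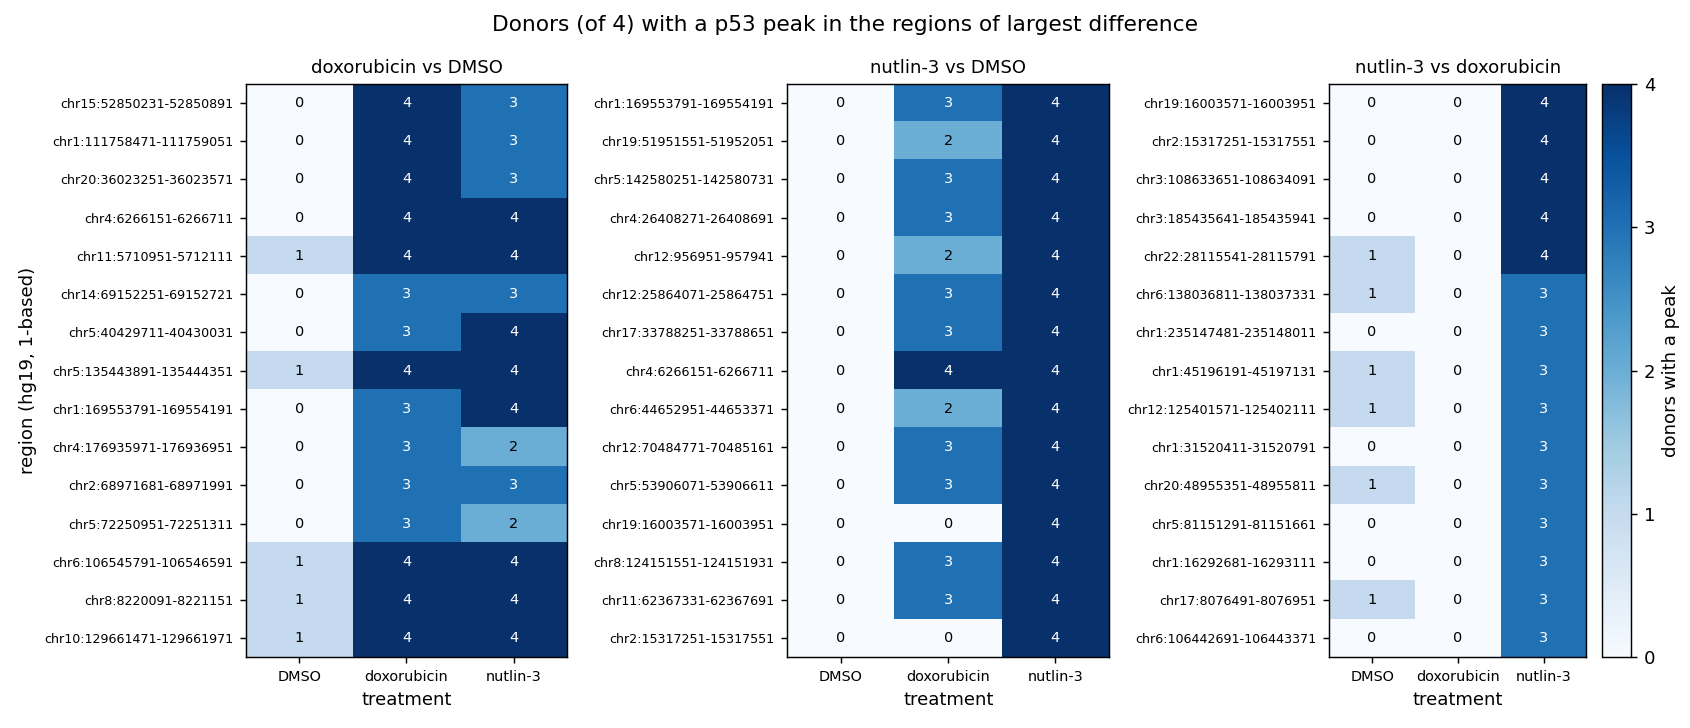
Number of donors out of 4 with a p53 peak (colour and digit) in each treatment (x axis) at the 15 regions of largest difference for each pair of treatments (y axis, hg19, 1-based positions). In the doxorubicin and DMSO panel every region had a peak in 2 or more nutlin-3 donors, and in the nutlin-3 and doxorubicin panel every region had 0 doxorubicin donors.

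The third comparison set the 2 drugs side by side, and most regions repeated with doxorubicin were also repeated with nutlin-3. Of the 721 regions in 3 or more doxorubicin donors, 613 (85.0%, Wilson 95% interval 82.2 to 87.4) were also in 3 or more nutlin-3 donors, and 720 had a peak in at least 1 nutlin-3 donor. The 613 were 63.3% of the 969 nutlin-3 regions, of which 885 (91.3%) had a peak in at least 1 doxorubicin donor. With peaks wider than the median alone, 13 doxorubicin regions were repeated and the common share was 23.1%. Among the 613 common regions, 113 had no DMSO peak, 435 had a peak in 1 DMSO list and 65 in 2 or more. In 431 of those 435 the peak came from the same DMSO list.

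Regions seen in every nutlin-3 donor and in no doxorubicin donor were few, while 84 were in 3 or more nutlin-3 donors and none with doxorubicin. All 4 nutlin-3 donors and 0 doxorubicin donors had a peak at 5 regions, which were chr19:16003571-16003951, chr2:15317251-15317551, chr3:108633651-108634091, chr3:185435641-185435941 and chr22:28115541-28115791, and 0 regions had the reverse. The first 4 had no DMSO peak, and the region of chromosome 22 had a peak in 1 DMSO donor. Regions with 3 nutlin-3 donors and 0 doxorubicin donors included chr6:138036811-138037331, chr1:235147481-235148011, chr1:45196191-45197131 and chr12:125401571-125402111. In 3 or more donors against at most 1, 182 regions were higher with nutlin-3 and 19 with doxorubicin.

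Within donors, 91 regions had a peak with nutlin-3 and not doxorubicin in at least 3 donors and none opposite, and 1 region had the reverse. Fisher's exact test passed 0 of 8243 regions after Benjamini-Hochberg adjustment (smallest adjusted p = 1, unadjusted p = 0.0286 for 5 regions). The log2 ratio of the number of peaks was 0.92 (exact two-sided permutation p = 0.486, adjusted p = 0.714, n = 4 and 4). With the same number of widest peaks, many of them taken at random at equal width, the direction turned, to 0 regions with nutlin-3 and 3 with doxorubicin. With peaks wider than the median the counts were 0 and 0. The count of 5 was 63 without nutlin-3 replicate 1, 21 without nutlin-3 replicate 3, 11 without doxorubicin replicate 1 and 10 without nutlin-3 replicate 2. The balance of 182 against 19 turned to 14 against 106 without nutlin-3 replicate 4, which had the longest list, to 22 against 68 without replicate 2 and to 37 against 58 without replicate 3 of nutlin-3. Without doxorubicin replicates 1, 2 and 4 it was 309, 297 and 288 against 0 (a treatment left with 3 lists must hold the peak in all 3). The direction was kept without nutlin-3 replicate 1, at 145 against 22, and without doxorubicin replicate 3, at 182 against 19.

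**Figure D3:**
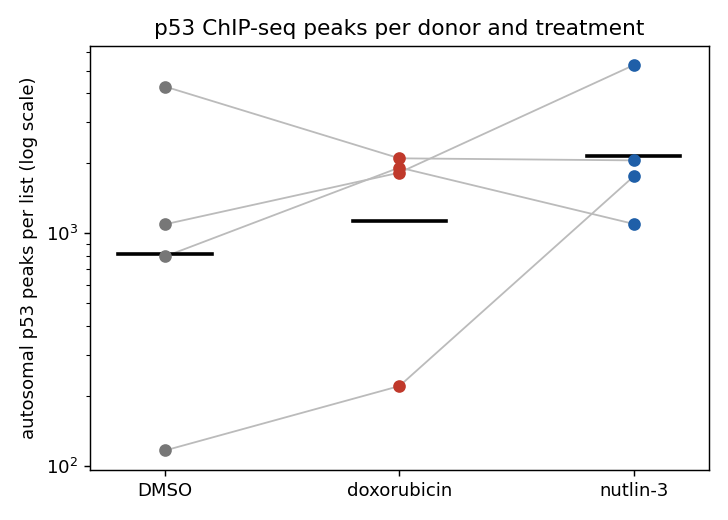
Autosomal p53 peaks per list (y axis, log scale) by treatment (x axis), with 1 point per donor, grey lines joining the lists of a donor and black bars at the geometric mean. The lists ran from 117 to 4264 peaks with DMSO, from 221 to 2099 with doxorubicin and from 1098 to 5270 with nutlin-3.

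Any pair of drug lists shared more regions than most pairs with a DMSO list. Overlap was the number of common regions as a percent of the shorter list. It averaged 64.5% between doxorubicin lists (6 pairs), 58.0% between nutlin-3 lists (6 pairs) and 59.8% between a doxorubicin and a nutlin-3 list (16 pairs). Doxorubicin pairs with the short list of replicate 3 ran from 79.1% to 80.9%, and those without it from 48.4% to 49.0%. Between a doxorubicin and a nutlin-3 list the range was 70.9% to 85.9% with that list and 46.7% to 70.3% without it. Nutlin-3 pairs ran from 45.6% to 72.9%. Between DMSO lists the overlap averaged 13.7% (6 pairs, 4.09 to 28.2). Between a DMSO and a doxorubicin list it was 25.2% and between a DMSO and a nutlin-3 list 26.3% (16 pairs each). Without 1 of the DMSO lists these means were 11.6% (5.63 to 24.1) and 15.5% (6.32 to 35.9) over 12 pairs each. Peaks that overlapped between drug lists also lay closer together, with a median distance between midpoints of 30 bp in the typical pair of drug lists and 60 bp in the typical pair of DMSO lists. Windows of the narrowest peak width placed to overlap at random had a median distance of 100 bp.

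Lists of the same treatment overlapped by 8.70 percentage points more than lists of different treatments from different donors (45.4% and 36.7%, exact permutation of treatments within donors, p = 0.037). Pairs of 2 drug lists were a larger part of the same-treatment pairs, so this does not show that lists resembled their own treatment. By kind of pair, DMSO lists overlapped each other less (13.7%) than they did doxorubicin (25.2%) or nutlin-3 lists (26.3%). Nutlin-3 lists overlapped each other by 58.0% and doxorubicin lists by 59.8%. Doxorubicin lists overlapped each other by 64.5%, highest in pairs with the short list of replicate 3. Means by kind include same-donor pairs. Lists of the same donor and different treatments overlapped by 1.68 points more than lists of different donors and different treatments (38.4% and 36.7%, exact permutation p = 0.417). Among lists of different donors, pairs of drug lists exceeded pairs with a DMSO list by 37.0 points (exact permutation p = 0.0247). This test was added after the lists were seen. The excess was 34.1, 36.8 and 31.4 points without replicates 1, 2 and 3, each with an exact permutation p of 0.0741. Without replicate 4 the excess was 45.5 points (exact p = 0.037). The difference between lists of the same and of different treatments fell to 4.41 points (p = 0.222, exact permutation) without replicate 3, and was 7.68 (p = 0.0556) without replicate 1 and 5.64 (p = 0.333) without replicate 2. Without replicate 4 it was 17.1 points (exact permutation p = 0.0278). With the Jaccard index it was 1.90 points (exact permutation p = 0.296) and for peaks wider than the median 2.05 points, neither past the threshold.

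**Figure D4:**
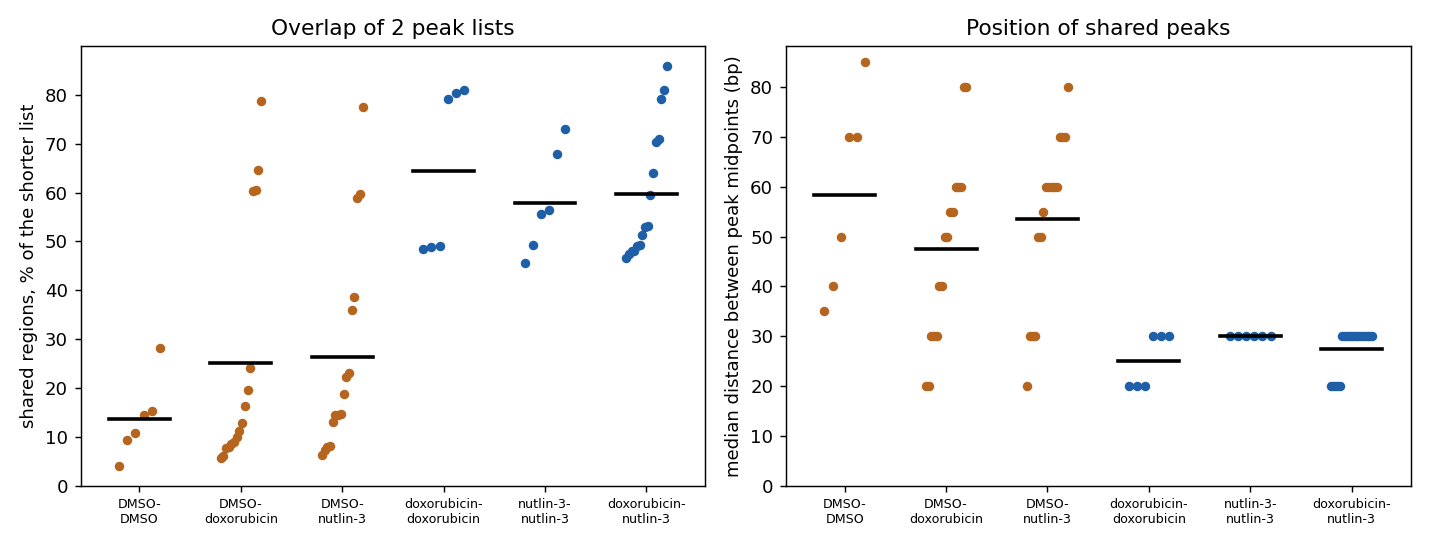
Left, common regions of 2 lists as a percent of the shorter list (y axis), and right, median distance in bp between the midpoints of overlapping peaks (y axis), for each kind of pair of lists (x axis), with 1 point per pair and black lines at the means. Pairs of drug lists (blue) ran from 45.6% to 85.9% overlap and from 20 to 30 bp, and pairs with a DMSO list (brown) from 4.09% to 78.6% and from 20 to 85 bp.

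To ask how much of each list was made of regions repeated among drug lists, a core set was drawn for each donor from the other donors, as the regions in 3 or more of their 6 drug lists. This measure was added after the lists were seen. DMSO lists had no part in choosing the core, so the choice favoured drug lists over DMSO lists. A short list also cannot hold many core regions, as DMSO replicate 3 had 117 regions against a core of 1430. Nutlin-3 lists held a peak at 68.9% ± 23.7 of the core regions (SD, n = 4), doxorubicin lists at 58.7% ± 31.1 and DMSO lists at 17.8% ± 27.3. In 3 of the 4 DMSO lists the value lay between 1.40% and 8.52%, and in the other it was 58.5%. Core regions made up 42.0% ± 15.96 of the regions in a nutlin-3 list, 55.2% ± 17.3 in a doxorubicin list and 20.5% ± 25.6 in a DMSO list (SD, n = 4). Recovery exceeded DMSO by 40.9 points with doxorubicin and by 51.1 points with nutlin-3 (exact two-sided permutation p = 0.0571 for each, adjusted p = 0.0857), which did not pass the threshold. Compared within donors, recovery was higher than with DMSO in 4 of 4 donors for each drug, and the exact sign-flip p was the smallest that test can give (adjusted p = 0.188). Nutlin-3 exceeded doxorubicin by 10.2 points (exact p = 0.6, adjusted p = 0.6), and without replicate 3 the difference was -4.54. The share of core regions did not separate any pair of treatments (exact p = 0.114, 0.2 and 0.429).

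**Figure D5:**
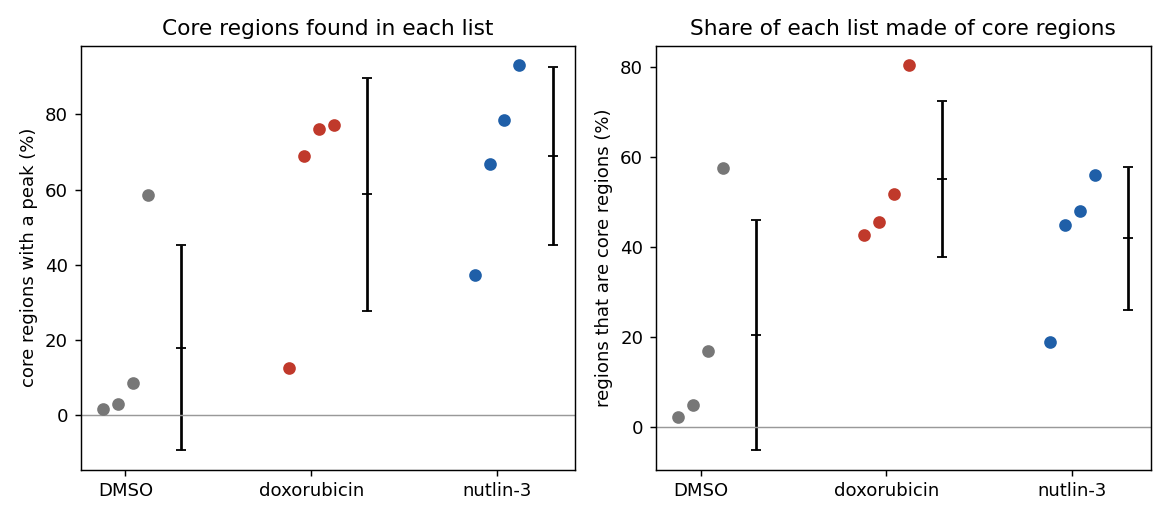
Percent of core regions with a peak in each list (left, y axis) and percent of each list's regions that are core regions (right, y axis) by treatment (x axis), with 1 point per donor in order of value and bars at the mean ± SD. With DMSO, 3 points lay between 1.40% and 8.52% on the left and 1 at 58.5%, inside the range of the drug lists.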

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

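The tests on core regions, on gene density, on list length and on other splits in this part were chosen after the results had been seen, except the thinning of the doxorubicin and nutlin-3 lists, whose outcome was set out beforehand. In 21 groups of 4 lists, 3 values stood apart from the rest of their group by Dixon's criterion, and chance gives about 1 in 20 groups. The core recovery of 1 DMSO list, 58.5%, was far above the nearest other, 8.52%. The shortest doxorubicin list, replicate 3, held 221 peaks against 1822 in the next. The same list had the lowest doxorubicin core recovery, 12.4% against 69.0% in the next, while 80.5% of its regions were core regions, the highest share of the 12 lists.

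In 1 DMSO list the regions resembled those of drug lists, with 57.7% of its regions in the core of the other donors, a share that p53 binding without added drug could give. An exchange of labels with a drug library was argued against, because 0 drug lists fell inside the range of the other 3 DMSO lists in both measures. A single wrong label remains open. So do reads from a drug library of the same donor: overlap with that donor's nutlin-3 list exceeded the mean with the other donors' nutlin-3 lists by 25.1 points, just above the 8.87 to 22.4 of the 6 drug lists of other donors measured against the same lists, and for doxorubicin the difference was -1.89, inside -16.2 to 1.14. No value here decides between leaked reads, a wrong label and p53 binding without drug, because sites particular to a donor would raise the same overlap and no read counts were used.

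The longest DMSO list, replicate 2 with 4264 peaks, was mostly regions of no other list (78.7%). Even scatter over the genome was argued against as the whole cause, since 26.4% (24.9 to 27.9) of these single-list regions lay on the 4 autosomes with most genes per Mb, which hold 12.7% of the length. p53 bound as in the drug cultures was argued against as well, because the list had a peak at 8.52% (7.04 to 10.3) of the core regions, below every drug list, the lowest of which had 12.4% (10.8 to 14.2) with 221 peaks. Preferential recovery of gene-dense, open chromatin may account for part of the list and stays open, as single-list regions of the other 11 lists ran from 10.1% to 26.0% on those autosomes. The 26.0% came from DMSO replicate 3, with only 50 such regions (15.9 to 39.6), and the next highest was 20.9% in nutlin-3 replicate 3. Gene density stands in for open chromatin in this comparison, and the input libraries were not used here.

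More regions were in 3 or more nutlin-3 donors and at most 1 doxorubicin donor than the reverse, by 163 (182 and 19). Longer nutlin-3 lists are a candidate explanation, and when both lists of a donor were thinned at random to the same number the difference became -91.48 (95% range of 100 draws -106 to -73.4). That value decides nothing by itself, because random thinning also removes strong shared sites from the long lists, which a lower sequencing depth would spare. The different action of the drugs stays open and was not tested.

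Among the 35 divisions of the 8 lists of each pair into 4 and 4, the real one included, at least 0.05 gave counts as large, so chance could not be excluded for any pair. For all 4 donors against 0, the doxorubicin and DMSO count of 4 was reached by 3 splits including the real one (highest other 359), the nutlin-3 and DMSO count of 75 by 2 (highest other 161) and the count of 5 between the drugs by 13 (highest other 31). For 3 or more donors against at most 1, the counts of 649, 901 and 182 were reached by 2, 2 and 14 splits, again with the real one, and 776, 978 and 414 were the highest others. Among the 8 splits that part the lists of every donor, the 4 and the 75 were the highest, with 0 and 2 next, and so were 649 and 901, with 535 and 596 next, while the drug pair's 5 and 182 were each reached by 3. The split with 359 regions exchanged 1 DMSO list with the short doxorubicin list, and the one with 161 exchanged the same DMSO list with nutlin-3 replicate 1, so these counts point to a structure of the lists that rests on that DMSO list, whose label and reads are left open above.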

How the results depend on the processing

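The broader criterion as its own result, single lists left out and thinning to at most 796 peaks were chosen after the data were seen. So were the core regions, the tests of repeated regions and the test of drug lists against DMSO. The remaining settings were planned. Trimming peaks to 200 bp and merging within 500 bp changed no call and moved no count by over 1.5 times. The number of peaks did not pass in any setting. With a donor left out and in the paired test it could not pass. The smallest p those tests can give lies above the threshold, so these failures carry no evidence. The ratio of doxorubicin to DMSO in peak number was reversed on the linear scale (-0.0499), where the longest DMSO list weighs most. Without single donors the log2 ratios ran from 0.21 to 0.97 (doxorubicin and DMSO), 0.56 to 2.21 (nutlin-3 and DMSO) and 0.23 to 1.50 (the drugs).

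Regions in all 4 donors against 0 depended on single lists, since a shorter list or fewer lists changes what the criterion asks. Without 1 donor or list they numbered 4 to 164 (doxorubicin over DMSO), 75 to 399 (nutlin-3 over DMSO), 5 to 91 (nutlin-3 over doxorubicin) and 0 to 2 (doxorubicin over nutlin-3). With 3 or more donors against at most 1 the counts were 649, 901 and 182 in these 3 directions, and 6, 4 and 19 in the opposite ones. The 6 and the 4 were capped by the 28 regions in 3 or more DMSO donors. Paired by donor (the replicate block), which also asked for only 3 donors with none opposite, the counts were 280, 683 and 91. In that setting 1 region was higher with doxorubicin than nutlin-3. The block changed no other call, but its tests of peak number, core regions and repeated regions could not pass at 4 donors. With peaks wider than the median alone the counts for all 4 donors against 0 were 0, 1 and 0. With the same number of widest peaks they were 5 for nutlin-3 over DMSO, 0 for nutlin-3 over doxorubicin and 3 in reverse. Many of those peaks were taken at random at equal width.

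Under the broader criterion, wide peaks gave 13, 20 and 11 regions, and 0, 0 and 5 in reverse; the block gave 280, 683 and 91, and 0, 0 and 1 in reverse. Single lists left out gave 120 to 699, 401 to 946 and 14 to 309, and 0 to 7, 0 to 6 and 0 to 106 in reverse. Regions in 3 or more donors without 1 donor, which then asks for all that remain, were 5 to 17 (DMSO), 173 to 717 (doxorubicin) and 445 to 871 (nutlin-3). For wide peaks they were 0, 13 and 20, for 2 or more donors 266, 1235 and 1952, for all 4 donors 4, 172 and 440, and thinned 7.39, 107 and 105. The percent common to the drugs ran from 82.7 to 92.0 without 1 donor and was 23.1 for wide peaks, which are few; the cause was not tested.

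The overlap by treatment was no longer past the threshold for wide peaks (2.05 points) or the Jaccard index (1.90, exact permutation p = 0.296), and ran from 4.41 to 17.1 points without 1 donor; the cause was not tested. The overlap by donor passed for wide peaks (3.74, exact permutation p = 0.0295, range over settings 0.0295 to 0.972) and ran from -0.64 to 4.05, reversed at -0.37 without replicate 1 and -0.64 without replicate 4. Wide peaks were only 3.42% of the 117 peaks of DMSO replicate 3 and 7.24% of the 221 of doxorubicin replicate 3. As overlap is a share of the shorter list, every wide-peak overlap with these lists rests on very few peaks. Drug lists exceeded pairs with DMSO by 31.4 to 45.5 points without 1 donor, past the threshold only without replicate 4, and by 13.5 points for wide peaks and 15.004 with the Jaccard index, both past it. Core recovery between the drugs ran from -4.54 to 24.3 and reversed without replicate 3, whose doxorubicin list was short. The added tests of repeated regions between pairs of treatments did not pass in any setting. Without 1 donor and in the block they could not pass, because the smallest p they can give lies above the threshold. The one-sided test over choices of the DMSO lists, given in Results, is a separate test and was below the threshold. Nutlin-3 minus doxorubicin ran from -224 (without replicate 3) to 697 without 1 donor. In the same settings the excess over DMSO ran from 162 to 700 (doxorubicin) and 440 to 859 (nutlin-3). No paired analysis was run for the common share. The motif, promoter and gene list results were not run. Unknown read depth limits every count.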

Other observations

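The 653 regions with a peak in 6 or more of the 8 drug lists were not spread evenly. In 14 places, holding 31 regions, 2 or more lay within 10000 bp of each other, whereas random placement gave 3.25 such regions on average and 15 at most in 1000 draws (one-sided permutation p = 0.001, the smallest they can give). Groups of 3 regions lay at chr6:36634921-36645371, chr4:78253971-78265861 and chr17:38694131-38704071. In the first of these, chr6:36634921-36635171, chr6:36644051-36644551 and chr6:36644731-36645371 each had a peak in all 8 drug lists and in 2, 3 and 2 DMSO donors. Pairs lay at chr19:47734491-47736241, chr13:48640721-48646741 and chr8:67025481-67036791, among others. A peak caller that divides 1 broad signal into several peaks would also place regions side by side.

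By chromosome length, chromosome 12 held 48 of the 653 regions where 30.3 were expected (exact binomial test, adjusted p = 0.0448 over 22 autosomes). Chromosome 2 held 38 where 55.2 were expected and chromosome 1 held 73 where 56.7 were expected, both with an adjusted p of 0.143. The binomial test treats neighbouring regions as independent. Lengths ran from the chromosome start to the end of the last peak, so stretches where no peak could be called count as length. The adjusted p of chromosome 12 lies close to the threshold.

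Of the 28 regions in 3 or more DMSO donors, 4 had a peak in 1 doxorubicin and 1 nutlin-3 donor alone. They were chr2:96823611-96823911, chr2:198063661-198063961, chr7:55602031-55602391 and chr7:157095041-157095421. The region chr11:65190111-65191811 had 3 DMSO, 1 doxorubicin and 2 nutlin-3 donors, and lay beside chr11:65188071-65188931, which had 3, 4 and 4. The neighbouring regions chr12:125422631-125423571 and chr12:125423881-125424711 had 3 DMSO donors each, with 4 and 1 doxorubicin donors and 4 and 3 nutlin-3 donors.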
